A study of Mus musculus with 4 samples.

How the data were processed

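Gene expression and T cell receptor sequences were measured in single CD45+ cells sorted from pancreatic islets of K392R and WT mice, with 1 library of each kind per genotype (4 samples). The deposited gene expression files hold raw UMI counts per gene and barcode for 27998 genes. The deposited receptor tables hold UMI and read counts per assembled contig, with V and J genes, CDR3 sequences and a clonotype identifier. According to the submitters, the authors used Cell Ranger, with no version given, and the mouse genome build mm10; no further step is stated. Every deposited barcode had at least 500 UMIs, and every deposited contig belonged to a called cell at high confidence. The labels give tissue, genotype and cell type, and do not give sex, strain or the number of mice.

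Choices of filters, classes, gene lists, comparisons, named-gene rule and alternatives were made before the data were examined, except where stated. Barcodes with at least 500 detected genes and at most 10% mitochondrial UMIs were kept. Doublets called by scrublet were left out, run in each library on barcodes with at least 200 genes and at most 20% mitochondrial UMIs at an expected rate of 8%. Counts were scaled to 10000 UMIs per cell and log-transformed. Clustering used 2000 variable genes, without receptor and immunoglobulin variable genes, Xist and Y genes, then 30 principal components, 15 neighbours and the Leiden method at resolution 1.0 with seed 1. T cell clusters were clustered again in the same way. This was done in Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.

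Clusters were named from fixed marker lists by mean standardised marker expression, and the suffix -like marks that names rest on markers alone. A name needed a lead of 0.5 over the next class (among T cell clusters, a score of 0.3 and the matching co-receptor in its place), at least 3 markers detected in 10% of cells, and no more markers of another class than of its own among the 10 leading genes. A cycling T cell cluster needed a cycling score of 1.5. These thresholds were set after the cluster scores had been seen. Clusters that met no name were left unnamed and kept in the denominators. A gate on UMIs (Cd8a or Cd8b1 without Cd4, or the reverse) gave a second definition of CD8 and CD4 T cells.

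Shares of cells are given with exact Clopper-Pearson 95% intervals. For expression, UMIs were summed per library and class and divided by the class total to give CPM. Log2 ratios of K392R over WT have exact conditional 95% intervals. Gene lists were summarised by the median log2 ratio of members with at least 20 UMIs over both libraries, with an interval from 1000 draws of the counts and a percentile among 10000 random lists matched in 20 expression bins. The percentile describes these libraries and is no test between genotypes. Named genes were the 10 highest and 10 lowest ratios of at least 1.5-fold, among genes with at least 100 UMIs and detected in at least 10% of cells of a library, in classes of at least 150 cells in each library. Immunoglobulin, receptor segment, mitochondrial, ribosomal protein, sex-linked, ambient-list and unnamed model genes were left out of that rule, and members of the fixed lists were named as members.

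The 26 fixed lists covered STAT3-induced genes, type I interferon response, interferon gamma response, cytotoxic effector, terminal effector memory, exhaustion, naive and stem-like T, tissue residency, chemokine and homing receptors, Tfh, Th1, Th17, Treg, proliferation, MHC class II, B cell activation, macrophage inflammation, glycolysis, dissociation and immediate early, heat shock, cytosolic ribosomal, mitochondrially encoded, beta cell, acinar, erythrocyte and sex-linked genes. Some genes stand in more than 1 list, and Ccl5, Nkg7 and Gzmk are also markers of the CD8 class.

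A clone was the cells of 1 library with the same V gene, J gene and nucleotide CDR3 of the most abundant productive alpha and beta chains. Clone shares were computed after drawing equal numbers of cells from each library 1000 times, and without drawing. Exact intervals for shares of cells by receptor treat cells as independent. Cells of 1 clone are counted together, so these intervals can be too narrow. V gene use was counted by clones in both CD8 classes, naming the 3 genes each way whose shares differed most. Receptors were joined to cells by barcode within each genotype, and 83.6% of K392R and 79.5% of WT T cells had both chains.

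Cells are not replicates and each genotype had 1 library, so no p-value, no count of changed genes and no variance between animals could be given. Intervals and floors (3 counts) cover counting error only. The expression step was tested on simulated data made from the CD8 effector-like totals of 5790 genes. Counts were drawn independently from the Poisson model behind the interval, so the simulation checks the computation and not the spread of UMIs between cells. Measured UMIs can lie in few cells: the 68 Gzmb UMIs of WT CD8 effector-like cells came from 9.23% of them. The interval is too narrow for such genes. The interval held the simulated ratio for 95.6% of 5590 unchanged genes, of which 2.1% reached 1.5-fold. All of the 67 genes simulated at 2-fold passed the 1.5-fold rule, and 43.3% of those at 1.5-fold did. A list of 15 genes simulated 2-fold higher had a median of 0.96 and a list of 15 unchanged genes -0.04.

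Alternatives covered the cell filters, doublets, Leiden resolutions 0.5 and 2.0, libraries clustered separately, UMI gates, and scaling by edgeR 4.0.16 (TMM) and DESeq2 1.42.0 (median of ratios) in R 4.3.3. They also covered totals without abundant genes, means per cell, cluster weighting, list member minimums, clone definitions and clones left out. A clustering of T cells without list genes and cells with at most 5% mitochondrial UMIs were added after seeing the data. So were the same B cell cluster make-up in both libraries, single T cell clusters, V gene use within each CD8 class and unnamed clusters counted as B cells. Cluster weights were the cell shares over both libraries together. Genes of NK-like cells other than Stat3, Socs3 and the type I interferon list were left out because the class held T cells, and classes below the cell minimum have no named genes.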

Results

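The study profiled immune cells of pancreatic islets from mice that carry 1 K392R copy of STAT3, the transcription factor that relays interleukin-6, interleukin-10 and interleukin-21 signals, and from wild-type (WT) mice. The series title names a human STAT3 mutation, type 1 diabetes and CD8 T cell tolerance, so the comparison asked how the islet infiltrate differed between the genotypes before diabetes. The mice were 8 to 10 weeks old and nondiabetic, and CD45+ (leukocyte) cells were sorted from islets. Each genotype had 1 gene expression library and 1 T cell receptor library, 4 samples in all. The labels do not say how many mice were pooled in a library. With 1 library per genotype there was no test between genotypes: every value below compares these 2 libraries, and every interval covers counting error only.

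The K392R gene expression library held 12261 barcodes with 82091066 UMIs, at a median of 4427 UMIs and 1635 genes per barcode. The WT library held 13228 barcodes with 79414446 UMIs, at a median of 3991 UMIs and 1526 genes. After filtering, 9888 K392R cells (80.65%) and 11227 WT cells (84.87%) were kept. More K392R barcodes than WT barcodes were lost to the filter on mitochondrial UMIs, 7.76% against 2.83%. The receptor tables held 5999 K392R and 5829 WT barcodes, of which 5155 and 4847 had a productive alpha and beta chain. Both libraries came out as male: Xist had 5 and 3 UMIs, and the Y-linked gene Ddx3y stood at 43.4 and 49.8 CPM (UMIs scaled to 1e6 per class or library).

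The first comparison concerned the altered gene itself. Stat3 (ENSMUSG00000004040) had log2 ratios, K392R over WT, from -0.33 to 0.13 in the T cell classes. In CD8 effector-like cells it stood at 195 CPM in K392R and 178 CPM in WT, a ratio of 0.13 (95% interval -0.08 to 0.35). The log2 ratio was 0.13 in Treg-like cells, -0.08 in CD4 effector-like cells and -0.11 in cycling T-like cells. It was below 0 in naive CD8-like cells (-0.29, -0.59 to -0.01), naive CD4-like cells (-0.33, -0.49 to -0.17) and plasma cell-like cells (-0.38, -0.70 to -0.05). It was above 0 in B-like cells (163 against 128 CPM, 0.35, 0.26 to 0.44), macrophage-like cells (0.43, 0.24 to 0.62), cDC2-like cells (0.24, 0.11 to 0.37) and mature DC-like cells (0.28, 0.02 to 0.54). In cDC1-like, neutrophil-like, pDC-like and NK-like cells the log2 ratios were 0.13, 0.42, 0.18 and 0.04, with intervals that included 0. The point mutation leaves the transcript in place, so these values do not check the genotype labels.

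Socs3, the feedback inhibitor that STAT3 induces, was higher in K392R in 11 of 12 classes, and in 9 of them the interval lay above 0. The widest difference was in B-like cells, with 116 CPM in K392R and 27.5 CPM in WT (log2 ratio 2.08, 1.91 to 2.25). In Treg-like cells it was 171 against 97.7 CPM (0.81), in cDC2-like cells 370 against 211 CPM (0.81), and in CD4 effector-like cells 216 against 150 CPM (0.53). CD8 effector-like cells stood at 185 against 137 CPM (0.43, 0.19 to 0.68). In naive CD8-like cells the ratio was -0.27 (-0.65 to 0.11). The list of STAT3-induced genes fixed for this work had a median log2 ratio of 0.28 (0.14 to 0.34) in CD8 effector-like cells, with 2 of its 16 measured members at least 1.5-fold higher and none at least 1.5-fold lower. The Il21r and Bcl3 members stood at 0.49 and 0.39. As means of per-cell CPM its median in these cells was 0.10. The same list was at 0.22 in Treg-like cells and 0.17 in B-like cells, and below 0 in naive CD8-like (-0.14) and naive CD4-like cells (-0.33). It did not follow Socs3 in CD4 effector-like (0.02) and cDC2-like cells (-0.01), and stood at -0.02 in macrophage-like and -0.04 in cycling T-like cells. With both libraries given the same cluster make-up, the naive CD4-like value was -0.04 and the Treg-like value 0.13, and with members of 5 or more UMIs the naive CD8-like value was -0.07.

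**Figure D1:**
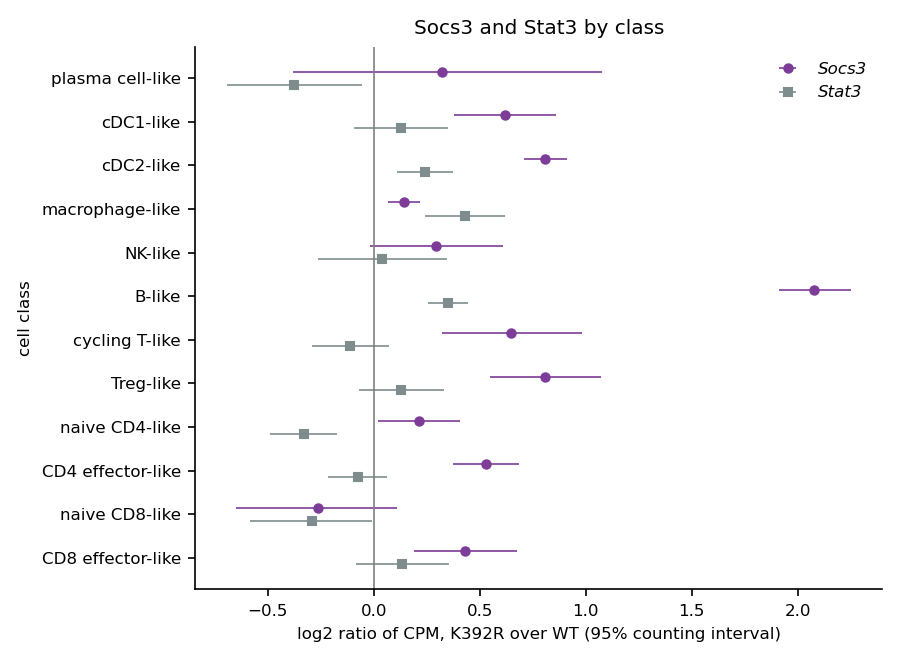
Log2 ratio of CPM, K392R over WT, for Socs3 (circles) and Stat3 (squares) in 12 cell classes, with 95% counting intervals as bars. Socs3 lies above 0 in 11 of the 12 classes and reaches 2.08 in B-like cells.

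The second comparison concerned which cells made up the infiltrate. CD8 effector-like cells were 7.68% (7.16 to 8.22, exact Clopper-Pearson interval) of kept K392R cells and 1.74% (1.5 to 2.0) of WT cells, 4.42 times the share. They were recognised by Cd8a, Cd8b1, Ccl5, Nkg7, Gzmk and Eomes, and comprised 759 K392R and 195 WT cells. Naive CD8-like cells went the other way, at 3.80% in K392R and 6.23% in WT. The 2 CD8 classes together held 24.18% of the T cells in K392R and 19.96% in WT, a difference of 4.22 points (2.52 to 5.91). The unnamed T cell cluster 14 lies outside both, with mean Cd8a and Cd8b1 of 452.3 CPM and Cd4 of 21.3 CPM. Its highest marker score was naive T, and it held 36 K392R and 150 WT cells. Leaving it unnamed therefore widened the 4.22 points and lowered the naive CD8-like share more in WT. Cells gated as CD8 by UMIs alone held 24.8% and 24.4%. Within those CD8-gated cells, 51.5% (48.6 to 54.5) were effector-like in K392R and 15.2% (13.1 to 17.5) in WT, while 29.9% and 59.2% were naive-like. With effector, exhaustion, naive, residency and homing genes left out of the clustering, the effector-like shares of CD8-gated cells were 52.5% and 17.2%.

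CD4 effector-like cells, recognised by Cd40lg, Icos and Tnfsf8, made up 9.57% (8.99 to 10.2) of K392R cells and 6.63% (6.17 to 7.10) of WT cells. This difference of 2.94 points went from 2.64 to 5.6 points under other settings. Cycling T-like cells, led by Birc5, Ube2c and Ccna2, were 2.52% against 1.13%. Antibody-secreting plasma cell-like cells (Jchain, Mzb1, Sdc1) were 2.34% against 1.00%, and macrophage-like cells (C1qa, C1qb, Apoe) were 3.96% (3.59 to 4.37) against 2.81% (2.52 to 3.14). Mature DC-like cells, marked by Fscn1, were lower in K392R, 0.64% against 1.47%. Treg-like cells, defined by Foxp3, Il2ra and Ikzf2, formed 3.90% against 4.37%. B-like cells made up 26.9% and 26.6% without the unnamed clusters below. The shares of cDC2-like cells (4.11% and 4.0%), cDC1-like cells (1.32% and 1.38%), pDC-like cells (0.60% and 0.59%) and NK-like cells (1.78% and 1.70%) had differences with intervals that included 0. Neutrophil-like cells were 0.92% and 0.65%, and fibroblast-like cells 0.15% and 0.11%. Naive CD4-like cells were 14.2% and 15.6%.

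Clusters that stayed without a name held 9.79% of K392R and 19.8% of WT cells. Most of them belonged to cluster 2, with B cell markers and a lead of the activation genes Egr1, Nr4a1, Myc and Cd83, at 7.41% against 16.9%. Unnamed T cell clusters held 5.85% and 4.21%. With the 3 unnamed clusters whose highest marker score was B added to the B-like cells, although they did not meet the naming rule, the shares were 35.34% and 44.96%, a difference of -9.63 points that came mostly from cluster 2. Under other settings the difference of the named B-like cells went from -4.52 to 3.52 points, below 0 with looser filters, with doublets kept and at the finest clustering. The macrophage-like difference was 0.01 points at the finest clustering, and the mature DC-like one was 0.20 points with each library clustered alone.

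**Figure D2:**
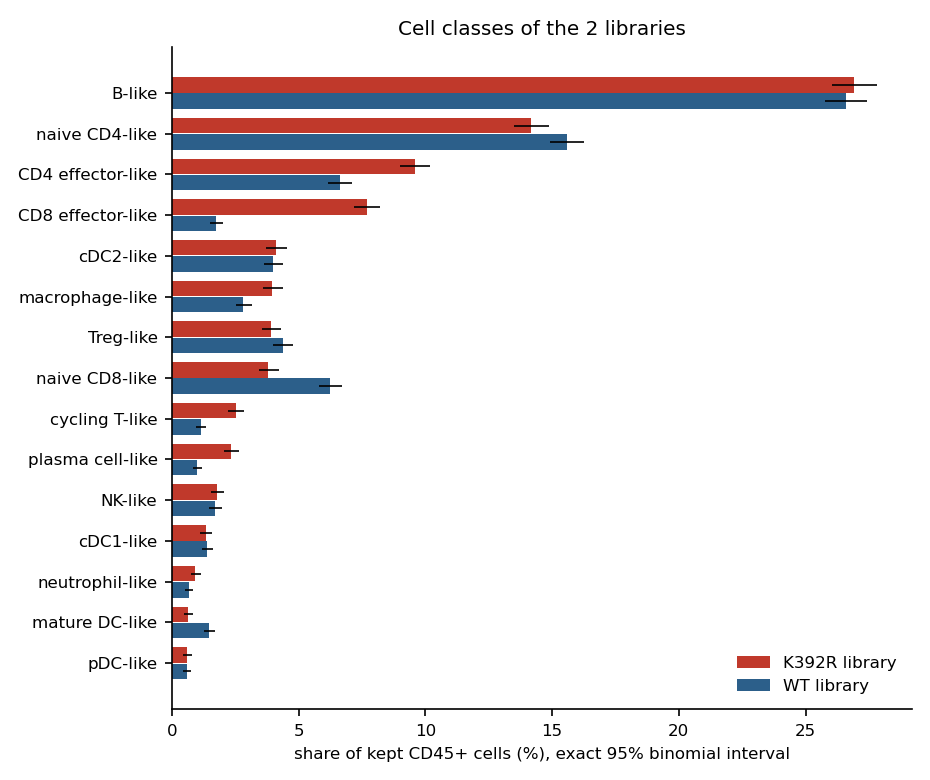
Share of kept CD45+ cells (%) in each named class except fibroblast-like cells, K392R library in red and WT library in blue, with exact 95% binomial intervals as black bars. CD8 effector-like cells are at 7.68% against 1.74% and naive CD8-like cells at 3.80% against 6.23%.

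The third comparison concerned gene expression in CD8 effector-like cells, with 4412613 UMIs in K392R and 1231841 in WT. Genes of cytotoxic and terminally differentiated effector cells were higher in K392R. Klrg1 (ENSMUSG00000030114), an inhibitory receptor of terminal effector cells, had 224 UMIs in K392R and 5 in WT, 50.8 against 4.06 CPM (log2 ratio 3.65, 2.40 to 5.28). Gzmb (ENSMUSG00000015437), which encodes the protease granzyme B, stood at 263 against 55.2 CPM (2.25, 1.90 to 2.63). Prf1 (ENSMUSG00000037202), the pore-forming protein perforin, stood at 67.3 against 25.2 CPM (1.42, 0.88 to 2.0). The effector transcription factor Zeb2 (ENSMUSG00000026872) was at 35.6 against 12.2 CPM (1.55, 0.78 to 2.42). The inhibitory receptor gene Lilrb4a was at 1.81 (0.83 to 2.98) and the sulfotransferase gene Chst11 at 1.62 (0.69 to 2.72).

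Wdr95 (1.35) and Dram2 (1.33) completed the higher side of the named genes, with Gzma (1.93) and Hopx (1.35), which are among the leading genes of T cell cluster 4 and are given only as such. T cell cluster 4 held 77.6% of the K392R and 62.1% of the WT cells of the class, and T cell cluster 3, led by Xcl1, Cd160, Ccl3, Ccl4 and Lag3, the rest. As a measure of RNA from other cells, B-like cells of the 2 libraries had 0.15 and 0 CPM of Gzmb, 2.05 and 1.11 CPM of Prf1, 0.51 and 0.08 CPM of Gzma, 0.22 and 0.08 CPM of Gzmk, and 18.4 and 3.89 CPM of Ccl5. Prf1 also stood at 24.8 and 28.4 CPM in naive CD8-like cells and at 22.0 and 17.3 CPM in naive CD4-like cells, near its WT level in CD8 effector-like cells. Macrophage-like cells had 2248 and 1016 CPM of Ccl5.

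On the lower side stood Nrn1 (30.8 against 109 CPM, -1.82, -2.17 to -1.46), Tspan32 (-1.39, -1.75 to -1.03), Lta, which encodes lymphotoxin alpha (-1.30, -1.85 to -0.74), and Ramp1, a calcitonin gene-related peptide receptor component (-1.24, -1.60 to -0.87). The median ratio of Lta over 8 classes was -0.93. Dapl1, a gene of naive T cells, was at -1.60. The interferon-induced Ifi27l2a was at 508 against 1019 CPM (-1.0, -1.10 to -0.90). Erdr1 (-1.02), Galk1 (-1.0) and Agpat5 (-0.99) followed. Hist1h2ap (-1.13) has near-identical histone copies. It was at least 1.5-fold lower in 9 of 12 classes, with a median of -0.99. With the UMIs of 12 classes added up it stood at -0.18 and the summed copies at -0.05. Such totals also follow the share of each class, so they do not show that the copies cancel within a class. The value of Hist1h2ap in CD8 effector-like cells is uncertain. Near-identical copies differed between the libraries in other families too, with Gm10260 at least 1.5-fold higher and Gm10116 at least 1.5-fold lower in all of 12 classes. Read length and software version of each library are not given in the sources used here, so ratios of genes with close copies, Lilrb4a among them, are uncertain.

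**Figure D3:**
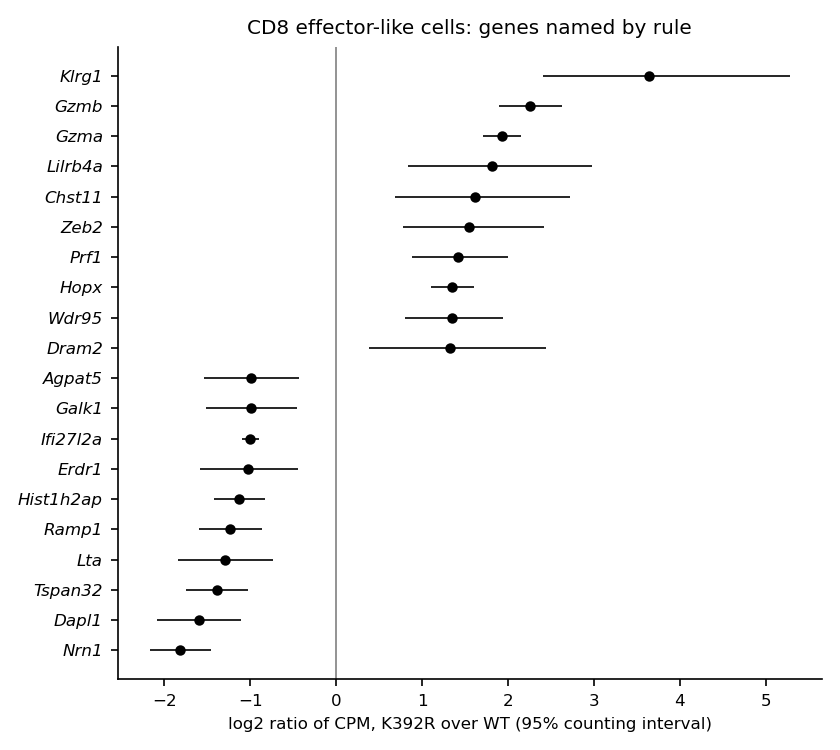
Log2 ratio of CPM, K392R over WT, in CD8 effector-like cells for the 10 highest and 10 lowest genes of the naming rule, with 95% counting intervals as bars. Klrg1, Gzmb and Prf1 lie at 3.65, 2.25 and 1.42, and Nrn1 lies at -1.82.

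Every one of the 18 measured members of the cytotoxic list was above 0 in CD8 effector-like cells, and 9 were at least 1.5-fold higher in K392R. Its median was 0.60 (0.48 to 0.76), above all of 10000 random lists of matched expression. The killer-cell receptor gene Klrd1 was at 0.65, and the class markers Ccl5 and Gzmk were at 1.10 and 0.99. Of 13 measured members of the terminal effector memory list, 6 were at least 1.5-fold higher, among them the sphingosine receptor S1pr5 (1.57) and the fractalkine receptor Cx3cr1 (0.85), with a median of 0.29, or 0.19 with the same cluster make-up in both libraries. The naive and stem-like list had a median of -0.26, with 3 of 13 members at least 1.5-fold lower, and Tcf7 stood at -0.25.

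Members of the exhaustion list went both ways, with 2 of 16 at least 1.5-fold higher, 1 at least 1.5-fold lower and a median of -0.16. Havcr2 was at 0.95 and Lag3 at 0.51, against -0.26 for Pdcd1 and -0.41 for Tox. That median was 0.06 when both libraries were given the same cluster make-up. The UMI-gated CD8 cells, which include naive cells, are another population, and there the cytotoxic, terminal effector and exhaustion medians were 1.498, 1.12 and 0.84.

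Among other lists in CD8 effector-like cells, type I interferon response genes had a median of -0.26, with 4 of 17 members at least 1.5-fold lower and Ifit1 at -1.29, and -0.08 as means of per-cell CPM, while interferon gamma response genes were at 0.22 with Gbp2 at 0.59, and at -0.06 in UMI-gated CD8 cells. The medians were 0.30 for Th1 genes (0.19 with the same cluster make-up), 0.10 (-0.02 to 0.29) for chemokine and homing receptors and 0.12 (-0.06 to 0.16) for glycolysis. The homing median was -0.04 with doublets kept, as means of per-cell CPM and with clustering without list genes. Medians were 0.15 for dissociation and immediate early genes (-0.01 as means of per-cell CPM), -0.14 for heat shock genes (-0.04 with doublets kept), and -0.08 for tissue residency. They were -0.09 for Tfh, -0.06 for Th17, -0.17 for Treg, -0.13 for proliferation, 0.07 for MHC class II, -0.10 for B cell activation and 0.32 (-0.02 to 0.63) for macrophage inflammation genes. Cytosolic ribosomal protein genes were at -0.16, mitochondrially encoded genes at 0.04 and the sex-linked list at -0.04.

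**Figure D4:**
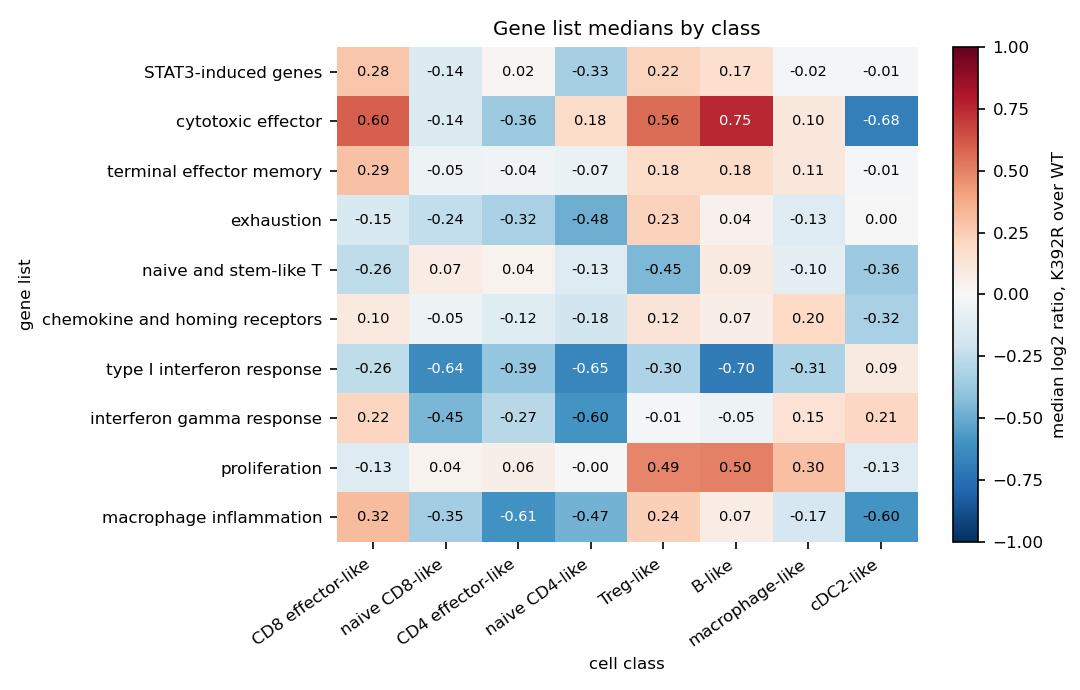
Median log2 ratio of CPM, K392R over WT, for 10 gene lists (vertical axis) in 8 cell classes (horizontal axis), with the value in each field and the colour scale from -1 to 1. The cytotoxic list is at 0.60 in CD8 effector-like cells and the type I interferon list at -0.70 in B-like cells.

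The fourth comparison concerned naive T cells, where interferon-induced genes were lower in K392R. In naive CD8-like cells (376 and 699 cells) the immunity-related GTPase genes Tgtp1 (40.3 against 104 CPM, -1.37, -1.78 to -0.98) and Tgtp2 (-1.07), the guanylate-binding protein gene Gbp7 (-1.15, -1.63 to -0.70) and the nucleic acid sensor Zbp1 (-1.03, -1.44 to -0.63) led the lower side. The type I interferon list had a median of -0.64 with 8 of 15 measured members at least 1.5-fold lower, and the interferon gamma list one of -0.45 with 7 of 16. Tgtp1 and Tgtp2 are close copies of each other. Coro2a (-1.06) and St6galnac2 (-1.05) were lower as well. The heat shock gene Hspa1b stood at -1.14 and its near-identical copy Hspa1a at 0.24, so the value is uncertain. The heat shock list as a whole was lower, with a median of -0.26 (-0.39 to -0.19) and 3 of 10 members at least 1.5-fold lower. Ccl5 was higher, at 568 against 193 CPM (1.56, 1.41 to 1.71), with a UMI in 19.7% and 8.44% of the cells at median depths of 4061 and 4084 UMIs, so a minority of cells carried it. In B-like cells, at 3999 and 3437 UMIs, it was found in 4.55% and 0.54%. Its median ratio over 12 classes was 1.19. The phosphodiesterase Pde2a (1.16), Cdc25b (1.00) and the integrin Itgb1 (0.89) were higher too.

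Naive CD4-like cells (1400 and 1750 cells) showed the same groups. The type I interferon median was -0.65, with 9 of 17 members at least 1.5-fold lower and none above 0. The interferon gamma median was -0.60, with 9 of 17, including Igtp (-0.72) and Gbp2 (-0.65). Lists of other cell types and states fell in the same cells, with medians of -0.66 for Treg, -0.65 for B cell activation, -0.59 for tissue residency, -0.48 for macrophage inflammation and -0.49 for exhaustion genes. The immediate early receptor-response gene Nr4a1 stood at 35.9 against 104 CPM (-1.53, -1.78 to -1.29), and Egr1 at -0.81. The dissociation and immediate early list as a whole was at -0.36, with 5 of 13 members at least 1.5-fold lower, and the heat shock list at -0.27. Mxd1 (-1.16), Tgtp1 (-1.15), P2ry10 (-1.12), Dusp5 (-1.11), Ctsw (-1.06) and Insig1 (-1.03) were lower. On the higher side, Trat1 (0.66), Isca2 (0.65), Thada (0.61) and Vps13a (0.60) passed the rule. T cell cluster 0, led by Igfbp4, Dapl1 and Lef1 among others, held 77.1% of the K392R and 55.9% of the WT cells. With both libraries given the same cluster make-up the medians were -0.38 for type I interferon, -0.34 for interferon gamma, -0.33 for Treg, -0.34 for tissue residency, -0.27 for exhaustion and -0.10 for dissociation and immediate early genes. The macrophage inflammation median was -0.01 with members of 5 or more UMIs, and the B cell activation median -0.24 with members of 100 or more. Without list genes in the clustering the type I interferon median was -0.21.

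The fifth comparison concerned CD4 effector-like cells (946 and 744 cells). Ifng, which encodes interferon gamma, was lower in K392R at 62.4 against 138 CPM (-1.14, -1.36 to -0.92). The interferon-responsive genes Irf8 (-1.34, -1.64 to -1.05) and Ly6a (-1.29, -1.44 to -1.15), the chemokine receptor Ccr8 (-1.27, -1.55 to -1.0), Bmpr2 (-1.19), Ms4a6c (-1.07), Cybb (-1.0) and the phosphatase Dusp4 (-0.99) were also lower. Myeloid and B cells express Irf8 as well, and myeloid cells Ms4a6c and Cybb. Genes of such cells were lower in the same class, with MHC class II at -0.38 (-0.93 to -0.02 over the alternatives) and Lyz2 at 7.13 against 13.9 CPM. The cells from which this RNA came are therefore uncertain. St6galnac1 (1.46, 0.93 to 2.02), Pde2a (1.31), Thada (1.15), the ADP-ribosyltransferase Art2b (1.11), Sigirr (1.09) and Dtx1 (0.87) were higher. The type I interferon median was -0.39 and the interferon gamma median -0.27. The exhaustion median was -0.32, the Treg list median -0.27 and the macrophage inflammation median -0.61 over 8 measured members, or -0.20 in UMI-gated CD4 cells. The ratios of Ccl3 (-2.75) and Ccl4 (-2.61) in this list rested on few cells, with a UMI in 0.74% and 0.94% of cells for Ccl3 and in 1.37% and 1.48% for Ccl4. The cytotoxic median of -0.36 took the other sign in several other settings, and UMI-gated CD4 cells had an exhaustion median of 0.09. With list genes left out of the clustering the type I interferon, interferon gamma and Treg medians were -0.25, -0.10 and -0.10. T cell cluster 10 held 62.3% of the K392R and 51.3% of the WT cells of this class, and T cell cluster 5, led by Nrn1 among others, the rest. T cell cluster 11 stayed unnamed and lies outside this class, although its Cd4 (321.6 CPM) exceeded its mean Cd8a and Cd8b1 (37.2 CPM). Cxcr6, Il18r1 and Tbx21 were among its leading genes, and it made up 4.50% of K392R and 1.83% of WT cells. Its type I interferon median was -0.24 (-0.37 to 0.04), on the same side as in CD4 effector-like cells. Medians for interferon gamma (0.165, 0.025 to 0.277), cytotoxic (0.155, 0.008 to 0.378) and MHC class II genes (0.72, 0.185 to 1.135) lay on the other side. STAT3-induced genes were at 0.25 (0.125 to 0.32), and exhaustion, Treg and macrophage inflammation genes each at -0.03. List medians of the CD4 effector-like class therefore did not all hold in this cluster, and Ifng may not either.

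Treg-like cells (386 and 491 cells) kept Foxp3 at the same level (-0.01). Higher in K392R were the chemokine receptors Cxcr6 (200.2 against 68.2 CPM, 1.55, 1.27 to 1.85) and Ccr2 (1.21), the decoy receptor Il1r2 (1.17, 0.85 to 1.5), Csf1 (1.37), Lilrb4a (1.65), Podnl1 (1.49) and Asb2 (1.20). Of 14 measured cytotoxic list members, 7 were at least 1.5-fold higher, with a median of 0.56, Gzmb at 79.5 against 25.1 CPM and Ccl5 at 1061 against 453 CPM. The Th17 list was at 0.69 and the naive and stem-like list at -0.45. Lower genes were Inadl (-1.08), Lta (-1.06), the interferon-induced Rtp4 (-1.05) and Tgtp1 (-1.03), and Bcl2 (-0.99), with a type I interferon median of -0.31. T cell cluster 7, led by Areg among others, held 57.8% of the K392R Treg-like cells, whereas T cell cluster 6 held most of the WT ones and cluster 7 only 41.1%. With the same cluster make-up in both libraries the exhaustion and Treg list medians of this class were -0.03 and -0.07, against 0.23 and 0.21, and the cytotoxic, Th17 and naive and stem-like medians were 0.29, 0.41 and -0.23. The proliferation median of 0.49 was -0.07 with doublets kept.

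The sixth comparison concerned B and myeloid cells. In B-like cells (2662 and 2986 cells) Socs3 had the highest ratio of the named genes (2.08). It was followed by S100a6 (215 against 67.6 CPM, 1.67, 1.56 to 1.78), Wfdc17 (1.55, 1.32 to 1.78), Plscr1 (1.36), the phospholipid transfer protein Pltp (1.32), Lgals1 (1.08) and the sterol pathway genes Insig1 (1.23) and Fdps (1.03). Interferon-induced genes were lower: Irf7, the regulator of type I interferon genes, stood at 10.8 against 34.6 CPM (-1.69, -1.97 to -1.41) and Ifi27l2a at 207 against 493 CPM (-1.26, -1.32 to -1.19). The type I interferon median was -0.70, with 9 of 17 members at least 1.5-fold lower, Rtp4 (-2.72) and Usp18 (-2.19) among them. The cholesterol exporters Abca1 (-1.04) and Abcg1 (-1.0), Ly6a (-1.04), Rgs2 (-1.03) and Zfp36l2 (-0.94) were lower too.

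All 17 proliferation genes were above 0 in B-like cells, 8 of them at least 1.5-fold higher, with a median of 0.50, and Birc5 stood at 30.1 against 11.8 CPM. That median was 0.22 with the same B cell cluster make-up in both libraries and 0.16 with doublets kept. Cluster 3 held 43.7% of K392R B-like cells and cluster 4 held 54.3% of WT ones. Cluster 5, led by Fcrl5 and Zbtb32 among others, held 16.0% of K392R and 10.5% of WT B-like cells. Its cycling score (0.9) was the highest of the B-like clusters. MHC class II genes were at -0.17 and B cell activation genes at -0.01. The unnamed cluster 2, with 7.41% of K392R and 16.9% of WT cells, lies outside this class. Its leading genes Egr1, Nr4a1, Myc, Ccr7 and Cd83 are members of the B cell activation list. The B-like value therefore does not show that activation was alike over all cells with B cell markers. Among list members with at least 100 UMIs the type I interferon median was -0.28.

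In macrophage-like cells the chitinase-like gene Chil1 was higher in K392R at 433 against 82.8 CPM (2.39, 2.22 to 2.55). Ifitm1 (1.98, 1.56 to 2.42), the protease Htra1 (1.94), the cholesterol 25-hydroxylase Ch25h (1.68), Ecm1 (1.63), Spon1 (1.52) and the phosphatidylserine receptor Timd4 (1.51) were higher as well. Ifit3 (4.92 against 25.2 CPM, -2.36, -3.05 to -1.72), the elastase gene Mmp12 (45.03 against 172 CPM, -1.93, -2.15 to -1.72), Pla2g2d (-1.71), Clmp (-1.60), Hilpda (-1.44) and the scavenger receptor Cd163 (-1.12) were lower. The type I interferon median was -0.31 with 8 of 20 members at least 1.5-fold lower, and the macrophage inflammation median was -0.17 (-0.09 with members of 5 or more UMIs), with Cxcl9 at 0.51 and Ccl3 at -0.71. None of the 15 immediate early genes was above 0, with a median of -0.40.

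Islet hormone RNA was abundant in macrophage-like cells, with insulin 2 (Ins2) at 564 and 499 CPM against 9.15 and 7.30 CPM in B-like cells. The beta cell list had a median of 1.11 in macrophage-like cells (0.70 with members of 5 or more UMIs), with 7 of 9 measured members at least 1.5-fold higher in K392R. Glucagon (Gcg) stood at 65.3 against 30.4 CPM, somatostatin (Sst) at 67.4 against 28.7 CPM and insulin 1 (Ins1) at 316 against 206 CPM. Exocrine acinar genes went the other way, with a median of -0.97 and Clps at 11.6 against 40.0 CPM. Erythrocyte RNA was sparse, with Hbb-bs at 42 UMIs in K392R and 5 in WT (0.64 and 0.08 CPM) over all kept cells, and Hba-a1 at 14 and 3 UMIs.

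In cDC2-like cells (406 and 449 cells), which form a single cluster led by Ifitm1 among others, Spon1 had 103 against 5 UMIs (4.52, 3.25 to 6.17). Upp1 (46.4 against 4.91 CPM, 3.24), the oxysterol hydroxylase Cyp7b1 (2.82), the serotonin receptor Htr7 (2.21) and Timd4 (1.94) were higher, while Xylt1 (-2.05), Ccl3 (-1.92), complement C3 (-1.64), Adgre1 (-1.50) and Lyz2 (1265 against 3190 CPM, -1.34) were lower. None of the 16 measured macrophage inflammation genes was above 0, and 8 were at least 1.5-fold lower, with a median of -0.60. The dissociation and immediate early list was at -0.44 in the same cells, with 5 of 15 members at least 1.5-fold lower and 1 above 0. The type I interferon list was not lower in these cells, with a median of 0.09 (-0.11 to 0.18) and 11 of 19 members above 0. Paired T cell receptors were found in 7.64% and 10.0% of cDC2-like cells, 5.61% and 4.43% of macrophage-like cells, 21.7% and 19.6% of plasma cell-like cells and 0.60% and 0.23% of B-like cells, against 88.7% and 87.2% of CD8 effector-like cells. NK-like cells carried them in 31.3% and 29.8% of cells, so this class mixed NK and T cells. Apart from Stat3, Socs3, the medians over 12 classes and a type I interferon median of 0.07 (-0.17 to 0.37), its genes are not reported.

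The seventh comparison concerned T cell clones, defined as cells of a library that share V and J genes and the nucleotide CDR3 of both chains. Among CD8 effector-like cells, 42.2% (38.4 to 46.0) of 673 paired K392R cells and 34.1% (27.0 to 41.8) of 170 paired WT cells belonged to clones of 2 or more cells. Cells of 1 clone enter this count together, so these intervals, which treat cells as independent, can be too narrow. At equal cell numbers the K392R share was 24.2% (16.5 to 32.4 over 1000 draws of 170 cells) against 34.1%, a difference of -9.88 points with an interval that included 0. The 10 largest clones held 16.9% (13.5 to 20.6) of drawn K392R cells and 23.5% of WT cells. The largest CD8 effector-like clone had 17 cells in K392R and 9 in WT. By cluster, T cell cluster 3 was the most clonal in both libraries, with 52.6% against 57.4% in clones of 2 or more cells. T cell cluster 4 stood at 14.1% against 12.7%, a difference of 1.35 points (-10.16 to 11.59). There the 10 largest clones held 1.31 points (-8.35 to 9.97) more in K392R, so neither interval excluded 0.

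Over both CD8 classes together the share in expanded clones was higher in K392R, 26.8% against 8.68%, and in UMI-gated CD8 cells 31.2% against 10.98%. These pooled shares carry the mix of classes. Effector-like cells were 673 of 954 paired cells of both classes in K392R and 170 of 691 in WT, and naive CD8-like cells were almost never in expanded clones. CD4 effector-like cells were at 22.6% against 30.2%, and T cell cluster 10 of this class at 5.78% against 6.35%. UMI-gated CD4 cells went the other way, at 15.6% against 14.4%, a difference of 1.22 points with an interval that included 0. Treg-like cells were at 11.2% against 6.41%, cycling T-like cells at 29.5% in both, and naive CD4-like cells at 0.36% and 0.24%. Of 281 naive CD8-like K392R cells none was in an expanded clone, which allows a share of up to 1.07%, against 0.22% in WT. Over all paired cells the shares were 22.3% and 13.8%. Cells of CD8 effector-like clones made up 59 of 236 paired cycling T-like cells in K392R (95% interval 19.6 to 31.0%) and 18.0% (11.7 to 26.0) in WT, against 0.91% and 0.26% of Treg-like cells. These shares were not computed at equal cell numbers. K392R had 673 paired CD8 effector-like cells to match and WT 170, so the libraries cannot be compared on them.

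**Figure D5:**
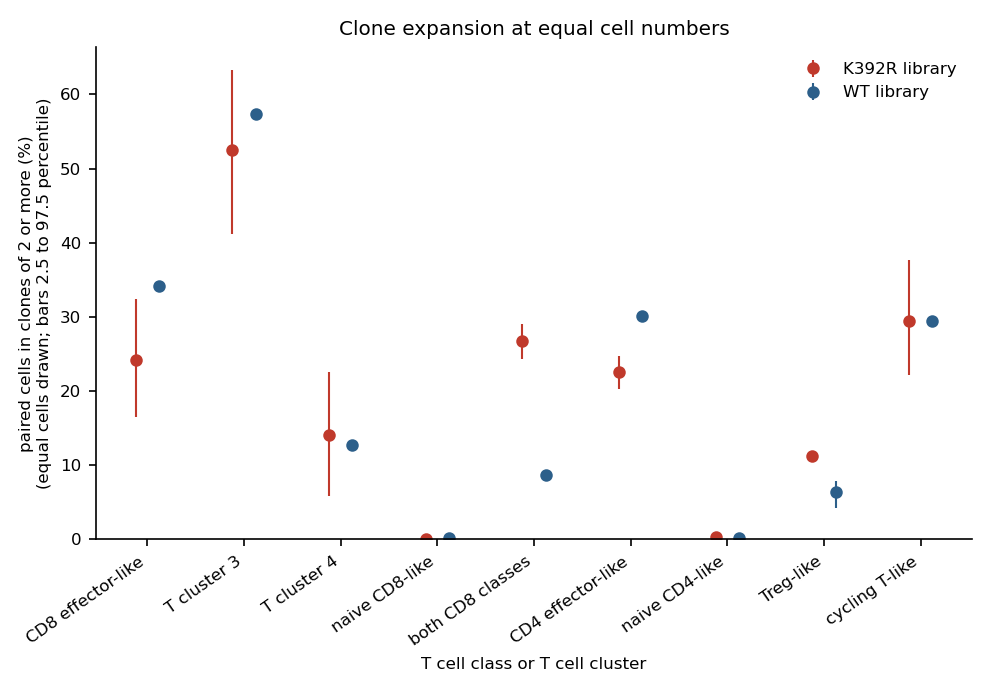
Share (%) of paired cells in clones of 2 or more cells, with the same number of cells drawn from each library, for T cell classes and clusters. Points are means over 1000 draws and bars the central 95% of the draws; CD8 effector-like cells lie at 24.2% in K392R and 34.1% in WT.

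Within each library, CD8 effector-like cells of clones of 3 or more cells (198 and 32 cells) were compared with cells of single-cell clones (389 and 112 cells). The 2 sets lay in different clusters, with 83 of 198 expanded and 55 of 389 single K392R cells, and 29 of 32 and 26 of 112 WT cells, in T cell cluster 3 and the rest in T cell cluster 4. Exhaustion genes were higher in the expanded cells, with a median log2 ratio of 0.98 (0.87 to 1.11) in K392R and 1.56 (1.28 to 1.75) in WT. Within T cell cluster 3 alone these medians were 0.79 and 1.00, and within T cell cluster 4 the K392R median was 0.43. Dissociation and immediate early genes were also higher in expanded cells (0.26 in K392R and 0.27 in WT), and cytosolic ribosomal protein genes lower (-0.12 and -0.15). Without the 3 largest clones these WT medians turned to -0.18 and 0.07. The inhibitory receptor Pdcd1 stood at 289 against 124 CPM in K392R and 457 against 132 CPM in WT. Tigit was at 0.96 and 2.10, Tox at 0.85 and 1.90, and Lag3 at 1.00 and 1.32. The chemokine receptor Ccr7 (-2.89 and -2.57) was lower, with naive and stem-like medians of -0.66 and -0.53, the WT one turning to 0.44 within T cell cluster 3. The cytotoxic medians were 0.23 (0.15 to 0.35) and 0.14 (-0.03 to 0.33), and 0.57 and 1.38 within T cell cluster 3. Gzma went the other way, at 410 against 603 CPM in K392R and at 0 against 196 CPM in WT (a log2 ratio of -3.40 or less). Gzmb stood at 311 against 231 CPM in K392R and at 4.97 against 63.2 CPM in WT. Without the 3 largest clones of each library, 10 expanded WT cells were left, and the WT exhaustion and cytotoxic medians were 0.45 and -0.15.

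V gene use in CD8 cells was compared by clones (752 and 651), of which 471 and 131 were CD8 effector-like. TRBV13-3 (12.6% and 9.06%), TRAV12D-2 (6.52% and 3.99%) and TRBV19 (9.57% and 7.37%) were higher in K392R, and TRBV13-2 (9.04% and 12.8%), TRBV14 (4.65% and 6.76%) and TRAV8D-2 (1.46% and 2.76%) lower. The intervals of the shares overlapped. Among CD8 effector-like clones alone, TRBV13-3 (13.4% and 13.7%), TRBV14 (4.88% and 4.58%) and TRAV8D-2 (1.27% and 0.76%) stood the other way. The invariant NKT alpha chain (TRAV11 with TRAJ18) was found in 25 and 29 paired cells, 0.48% and 0.60%, and the MAIT alpha chain (TRAV1 with TRAJ33) in 1 and 3. TRAV16-family chains joined to TRAJ42 are known from islet-reactive CD8 T cells of NOD mice. They made up 5.2% (3.65 to 7.16) of CD8 effector-like cells in K392R and 6.47% (3.27 to 11.3) in WT. These cells came from 16 and 5 clones, 3.4% and 3.82% of the clones, so intervals by cell can be too narrow. The chains made up 0.36% and 0.19% of naive CD8-like cells. Cycling T-like cells had them in 6.78% and 7.38%. Within the CD8 effector-like class, T cell cluster 3 held most of them, with 31 of 157 cells (19.8%) in K392R and 11 of 68 (16.2%) in WT. T cell cluster 4 had 0.78% in K392R and 0 of 102 cells in WT, which allows up to 2.94% by the floor of 3 counts (exact upper limit 3.55%).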

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

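The search for lists of opposite sign was chosen only after the values were seen, and none of the differences between classes was tested. It covered 25 lists in 8 classes, 192 values in all, of which 86 had an interval without 0 and the same sign in the alternatives run. Among these 86 values, 8 of the 25 lists had medians of opposite sign in different classes.

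STAT3-induced genes had a median log2 ratio, K392R over WT, of 0.279 in CD8 effector-like cells and -0.334 in naive CD4-like cells. Interferon gamma response genes were at 0.21 in cDC2-like cells and -0.6 in naive CD4-like cells. MHC class II genes were at 0.187 in Treg-like and -0.382 in CD4 effector-like cells, and macrophage inflammation genes at 0.24 and -0.607 in the same classes. Naive and stem-like genes were at 0.087 in B-like cells and -0.447 in Treg-like cells. Chemokine and homing receptors were at 0.196 in macrophage-like and -0.323 in cDC2-like cells. Glycolysis genes were at 0.239 in macrophage-like and -0.162 in naive CD8-like cells, and cytosolic ribosomal protein genes at 0.069 in naive CD4-like and -0.169 in cDC2-like cells. Several of these values came nearer 0 in an alternative, which need not be the same one in both classes. The value nearest 0 was -0.042 for STAT3-induced genes in naive CD4-like cells, with the same cluster make-up in both libraries. It was 0.1 in CD8 effector-like cells, as means of per-cell CPM. It was -0.02 for MHC class II genes in CD4 effector-like cells and 0.107 in Treg-like cells. For macrophage inflammation it was 0.027 in Treg-like and -0.198 in CD4 effector-like cells, and for interferon gamma 0.137 in cDC2-like and -0.343 in naive CD4-like cells. It was -0.233 for naive and stem-like genes in Treg-like cells, -0.131 for homing receptors in cDC2-like cells and -0.073 for glycolysis in naive CD8-like cells.

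Signals outside the compared measurements were RNA of cells that a CD45 sort should remove and receptors without a classified cell. Ins2, which beta cells make, stood at 564.29 CPM in K392R and 499.3 CPM in WT macrophage-like cells. Paired receptors were also found on barcodes that the filters left out, 975 in K392R and 1020 in WT.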

How the results depend on the processing

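The settings T cells clustered without list genes, cells of at most 5% mitochondrial UMIs and the same B cell cluster make-up were chosen only after the data were seen. So were CD8 classes together, single T cell clusters, V genes in each CD8 class and unnamed clusters counted as B. No paired analysis was possible because each genotype had 1 library, and leaving out a replicate was not possible for the same reason. Of 42 values that answer a comparison, 33 had an interval without 0, and 27 of these kept their sign in every alternative run. Over all alternatives of the 42, 244 values stayed within the interval, 64 moved and 8 reversed. For other lists and genes the numbers were 2641, 318 and 25. Counts for the 42 include clone values over all paired cells, another population than the CD8 or CD4 effector-like cells. Reversed means a changed sign where the interval lacked 0; where it included 0, a changed sign counts as moved outside the interval (clone differences of CD8 effector-like cells, -9.88 and -6.61) and as staying inside it (TRBV14, -2.11 and 0.3 in CD8 effector clones). The CD8 effector-like difference stayed between 5.77 and 6.24 points of CD45+ cells, and the type I interferon median between -0.675 and -0.516 in naive CD8-like cells. Libraries clustered separately gave no value for CD8 effector-like, naive CD8-like and NK-like cells. The WT cells formed an unnamed cluster of 452 cells led by NK and CD8 markers. Another of 686 cells, led by Cd8b1 and Cd8a among others, also stayed unnamed, with naive T and CD8 T scores of 0.66 and 0.62. The comparison of ambient genes between classes gives no new ratio. Small classes limit precision: 10 expanded WT cells remained without the 3 largest clones. For the values below the cause was not tested.

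Differences of shares are in points, K392R minus WT. With at least 200 genes and at most 20% mitochondrial UMIs, B was -3.13. With unnamed B-scored clusters counted as B, it was -9.63. With at least 1000 genes, CD4 effector was 5.6 of CD45+ and 8.45 of T cells. With doublets kept, B was -3.43, naive CD8 -3.16 (-10.59 of T cells) and the CD8 classes 2.02 of T cells. At resolution 0.5, CD4 effector was 5.35 (7.73 of T cells), naive CD8 -3.47 (-10.37) and the CD8 classes 1.9. At resolution 2.0, B was -4.52, macrophage 0.01, naive CD8 -6.24 of T cells and the CD8 classes 6.01. With libraries clustered separately, B was 3.52, CD4 effector 4.9 (5.44 of T cells), macrophage 1.7 and mature DC 0.2, a reversal. With T cells clustered without list genes, CD4 effector was 5.45 (8.08 of T cells). By UMI gate the CD8 share of T cells was 0.48.

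List medians are log2 ratios. In CD8 effector-like cells the UMI gate gave STAT3-induced 0.371, cytotoxic 1.498, terminal effector 1.118, naive and stem-like -0.788 and homing 0.386, and reversed exhaustion (0.837), interferon gamma (-0.058), mitochondrially encoded (-0.087) and Hist1h2ap (0.25). Means of per-cell CPM gave STAT3-induced 0.1, exhaustion -0.3, homing -0.037 and immediate early -0.012, a reversal. Doublets kept gave exhaustion -0.022 and homing -0.042. The same sub-cluster make-up in both libraries gave cytotoxic 0.463 and reversed exhaustion (0.06). Without the 10 largest clones cytotoxic was 0.427, exhaustion -0.038 and homing 0.326. Clustering without list genes gave homing -0.039, and totals without abundant genes reversed mitochondrially encoded (-0.024).

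In other classes, the cytotoxic list of CD4 effector-like cells reversed with doublets kept (0.159), by CD4 gate (0.315), with members of 5 or more UMIs (0.195) and with clustering without list genes (0.547). The CD4 gate also reversed exhaustion (0.085), homing (0.261) and ribosomal (-0.022). Doublets kept reversed Tfh in naive CD8 (-0.001), proliferation in Treg (-0.071), immediate early in B (-0.072), tissue residency in macrophage (0.08), and cytotoxic (0.396) and proliferation (0.026) in cDC2. The same sub-cluster make-up in both libraries reversed exhaustion (-0.028) and the Treg list (-0.065) in Treg. It gave type I interferon -0.384 in naive CD4, where clustering without list genes gave -0.209. With members of 100 or more UMIs, B had type I interferon -0.283 and cytotoxic -0.011, a reversal.

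For clones, differences are in points for expanded clones and then the 10 largest clones. CD8 effector was 20.2 and 4.71 by UMI gate, 8.52 and 0.74 over all paired cells, 1.35 and 1.31 in T cell cluster 4 alone, and 18.12 and 4.04 with both CD8 classes together. CD4 effector reversed to 1.22 by gate (-0.06 for the 10 largest). It was -0.57 and -0.15 in T cell cluster 10 alone, and -0.32 for the largest clone alone. The 8.52 and 0.74 over all paired cells were counted as reversals for CD4 effector too. They cover every T cell class and barcodes left out, so they are no second definition of CD8 or CD4 effector-like cells. For expanded against single WT cells, leaving out the 3 largest clones gave exhaustion 0.45 and cytotoxic -0.152, and reversed ribosomal (0.067), immediate early (-0.176) and macrophage inflammation (-0.127). Clones of 2 or more gave exhaustion 1.194. Within T cell cluster 3, K392R had cytotoxic 0.571 and exhaustion 0.785, WT had cytotoxic 1.377 and exhaustion 1.003, and WT reversed naive and stem-like (0.44) and the Treg list (-0.016). Within T cell cluster 4, K392R had exhaustion 0.425 and naive and stem-like -0.443. Among CD8 effector clones alone TRBV13-3 reversed (-0.36) and TRAV8D-2 was 0.51. T cell cluster 4 had too few expanded WT cells (3) for a value.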

Other observations

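For the patterns weighed here, the tests on dilution, on filter losses, on free RNA, on scaling and on the shared receptor were chosen only after the result was seen. Cycling T-like cells (249 and 127 cells), which share their clones with CD8 effector-like cells more often than naive CD8-like, Treg-like and CD4 effector-like cells did, had a cytotoxic median of 1.31 (1.10 to 1.44), with 16 of 18 members at least 1.5-fold higher in K392R. Their naive and stem-like median was -0.65, with 7 of 13 members at least 1.5-fold lower. The class pools cycling T cells of several kinds. Treg genes were at -0.18 (-0.28 to -0.07) and Tfh genes at -0.15. Of paired cells, 59 of 236 in K392R and 22 of 122 in WT belonged to CD8 effector-like clones, at unequal numbers of CD8 effector-like cells. A different mix of kinds was not separated from a change within 1 kind. T cell cluster 11, unnamed, with more Cd4 than Cd8 RNA and led by Gna15, Cxcr6 and Il18r1 among others, made up 4.50% of K392R and 1.83% of WT cells. In it the leukocyte immunoglobulin-like receptor gene Lilr4b stood at 44.8 against 8.98 CPM (2.32, 1.33 to 3.49), the STAT3-list member Bcl3 at 108 against 48.9 CPM (1.15, 0.70 to 1.62) and Jak3, a kinase of common gamma chain receptors, at 0.89. Cd8b1 (-1.82), Ccr7 (-1.33) and Xcl1 (-1.19) were lower.

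Cluster 2, the unnamed cluster with B cell markers led by Egr1, Nr4a1 and Myc among others, also had higher Socs3 in K392R at 196 against 60.2 CPM (1.71, 1.53 to 1.88). Plscr1 (2.02, 1.70 to 2.33), Wfdc17 (1.28), the signalling receptor Slamf1 (1.12) and the transcription factor Batf (1.12) were higher, and the G protein regulators Rgs1 (-1.64) and Rgs2 (-1.04) were lower. Its type I interferon median was -0.34. Ccdc85b had a median ratio of 1.40 over 12 classes and Tsc22d3 of -0.80, and the near-identical gene copies Hist2h2aa1 and Gm10116 stood at -1.07 and -1.05, values that are uncertain.

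The larger share of CD8 effector-like cells in K392R could come from a WT library diluted by naive or B cells, from losses at the filters, or from differences between single animals. Dilution would leave the ratio of CD8 effector-like to CD4 effector-like cells alike, whereas it was 0.80 in K392R and 0.26 in WT, a ratio of 3.06 (2.55 to 3.68). With all K392R barcodes that were left out counted as other cells, the share was 6.19%, above the WT upper limit of 2.0%. With 1 library per genotype, a difference between single animals or preparations and the genotype cannot be told apart.

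The lower type I interferon genes of K392R, seen in B-like, macrophage-like and most T cell classes and not in cDC2-like (0.09) or NK-like cells (0.07), could come from free RNA in the WT library, from a few responding cells, or from scaling. Free RNA of 1 source would add alike to each class, whereas with K392R scaled to the WT mean depth of each class the WT excess was 1.92 UMIs per cell (1.69 to 2.14) in naive CD8-like cells and 0.53 (0.46 to 0.60) in B-like cells, 3.64 times as many. Without this scaling the excess was 1.97 and 0.13 UMIs per cell. These classes had the highest and lowest excess of those compared. The others were alike at equal depth, with 1.14 (1.03 to 1.26) in naive CD4-like, 1.12 (0.94 to 1.31) in CD4 effector-like and 1.07 (0.79 to 1.35) in Treg-like cells. Without the 5% of B-like cells with the highest share of these UMIs the B-like median over 17 members was -0.485. This was not computed in T cell classes. The unnamed T cell cluster 2, led by Ifit3, Ifit3b and Isg15 among others, lies outside those classes with 8 K392R and 3 WT cells. Its effect on their medians was not tested. CPM divides out the depth of a library, so on scaling random lists can show only a shift of the class totals by other genes. Such a shift would move other genes alike, whereas random lists of matched expression had a median of -0.016 in B-like cells. The interferon median was -0.70 (-1.19 to -0.35) there. These values argue against free RNA added alike to every class as the whole cause. In B-like cells they argue against a few responding cells and against such a shift of totals, each as the whole cause. Having 1 library per genotype leaves animals, preparations and genotype as explanations that cannot be told apart.

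The receptor pair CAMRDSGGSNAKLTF (TRAV16N with TRAJ42) and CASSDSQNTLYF (TRBV13-3 with TRBJ2-4) was found in 19 K392R and 15 WT cells, including 9 and 4 CD8 effector-like cells, all in T cell cluster 3. Carry-over between libraries would bring other large clones along, but 0 of 87 other clones of 5 or more cells and 1 of 514 of 2 or more were found in both; that clone had 1 K392R and 4 WT cells. Of 6 amino acid pairs found in both, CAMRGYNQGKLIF with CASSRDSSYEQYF had 24 and 16 cells, mostly CD4 effector-like (17 and 10). A hypothesis is that the pair may arise by recurrent rearrangement and be kept by selection in the effector pool. It was coded by 3 nucleotide sequences, of which 1 was found in both libraries and made up most of its cells (14 in K392R and 11 in WT), and TRAV16-family chains with TRAJ42 made up 3.49% (2.17 to 5.28) of CD8 effector-like clones and 0.25% (0.03 to 0.90) of naive CD8-like clones. The specificity of the receptor was not measured.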
